A study of Homo sapiens with 4 samples.

How the data were processed

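The series compares 2 siNC and 2 siPC4 libraries of Huh7 cells, made from total RNA with an Illumina TruSeq RNA kit 48 h after transfection, per the labels' protocols. Reads were checked with FastQC and aligned to hg19 with TopHat2, per the submitters' processing notes, which give no versions. The counting tool, the annotation and the normalization are not given in the sources used here. The authors deposited 2 tables of all genes and 2 tables of called genes, 1 of each per pair of libraries.

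The unit of the authors' expression values is not named in the file headers and was taken from the values. The deposited values are TPM. Each library summed to between 996343 and 996814, low values shared no common step, and values under 1 were written as 0. A table listed only genes at 1 or more in at least 1 of its 2 libraries. TPM keeps no depth, so no interval or detection limit that needs read counts is given. The log2 fold changes deposited by the authors equal the log2 of the 2 listed values. Where a value is listed as 0 they imply a value between 0.03 and 1. The p-values and q-values deposited by the authors come from 1 library against 1 by a test the file headers do not name, and their ranks followed those of a binomial test on rounded TPM (Spearman's rho 0.985 and 0.981). The authors' tables of called genes hold the genes with q under 0.05 and an absolute log2 change of at least 1, which matched all 1441 and all 991 calls.

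Samples were grouped by their titles. The columns of the first table of all genes carry other names than its table of called genes, which repeats the values for all 1441 called genes (relative tolerance 1e-06). The control and knockdown columns are told apart by name in both. The treatment protocol lists siPC4-1 and siPC4-2 beside siNC as siRNAs, but it is not settled whether the 2 siPC4 libraries received different siRNA sequences. The tables were joined by the gene link each row carries. Of the 16159 genes in both, 20 had a different symbol, since the symbols of the second table held 21 date-like entries, and 5 a different position. The first table's were used. Genes in 1 table only (1439 and 1730) were left out of the main comparison.

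The main test was limma 3.58.1 in R 4.3.3 (eBayes with a mean-variance trend, two-sided) on log2(TPM + 1) over all 4 libraries, with the replicate number, which is also the table, as a block, and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. "Rose" and "fell" are used of genes past this threshold. The block was chosen because the authors compared siNC and siPC4 of the same number in tables of their own. Deviations from the group means correlated at 0.673 between libraries of the same number, a value over 2 pairs only. A filter of at least 1 TPM in at least 2 libraries removed 0 genes. With the block a gene has a single residual degree of freedom, and 4.83 in all with the prior. No count test fits these values.

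Lists of genes (26) were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Each list was tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry, adjusted over the 26 lists. Camera called 13 lists, 4 higher and 9 lower. With an estimated correlation it called 0, with a smallest adjusted p of 0.649, and fry called 1. The preset takes the genes of a list as nearly independent, so where they move together its p-values are too small as a measure of the libraries. The estimated setting rests on a single residual degree of freedom, so a list it does not call may still have changed. fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. Within a pair, a list's median was placed among 10000 random lists matched on mean expression in 20 bins. Genes were named by a fixed rule: SUB1, the members of the 2 lists in the series title that passed and the D-type cyclins, the 10 largest rises and falls among genes past the threshold, up to 4 members of every other list with the largest smaller change of the 2 pairs in one direction, and the 3 largest rises and falls among the authors' calls in each pair. Some genes that the rule takes are not reported here.

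The tests were run on simulated data with the real genes' levels. Each gene's spread was drawn from the prior of the limma fit, with normal errors that were independent between genes. That is the model limma assumes. Of 15048 simulated genes, 200 were changed, and limma recovered 38 of 100 changed by 1 and 97 of 100 changed by 2 on the log2 scale, with 15 calls among unchanged genes. With no change it called 0. With the real number of changes (4165 genes) it made 3263 calls, of which 3.65% were false. With the hepatocyte list lowered by 1 among 15025 simulated genes, camera gave an adjusted p of 1.77e-52 for it and called 1 other list, while with an estimated correlation the adjusted p for the lowered list was 0.902. The estimated correlation thus missed a list known to be changed. The simulated genes were not correlated, so these figures cannot show how often limma or camera calls falsely among correlated genes.

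The alternatives were no replicate block, median scaling, quantile normalization, no filter, at least 5 TPM in 2 libraries, a pseudocount of 0.1 or 5, no trend, each library left out, crossed pairs and stricter author calls. Chosen after the data had been seen were protein-coding genes only, values under 1 restored from the authors' log2 changes, at least 1 TPM in all 4 libraries, and mitochondrial and rRNA genes left out. For the closing tests, transcripts, proteins and 3' UTRs came from GENCODE 29, whose build differs from that of the files, so that it was used by symbol only and none of its coordinates are given. Of 12353 protein-coding genes tested, 12088 (97.9%) had a reference transcript. That part used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and the plots matplotlib 3.10.9. Its word search was checked by lowering genes with 1 word by 0.4 on the log2 scale among 11780 genes with shuffled changes, where that word came out first with a difference of -0.403. A class difference of -0.5 planted among 12118 genes with shuffled changes came out as -0.475.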

Results

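Gene expression was measured by RNA sequencing of total RNA from Huh7, a line of human hepatocellular carcinoma cells, 48 h after transfection with small interfering RNA. The 4 libraries form 2 groups of 2. One group received a control siRNA (siNC) and the other siRNA against PC4. PC4, the protein encoded by SUB1, is a coactivator of RNA polymerase II transcription that binds single-stranded DNA. The treatment protocol lists siPC4-1 and siPC4-2 beside siNC as siRNAs, so the 2 siPC4 libraries may have received 2 different siRNAs. The libraries were deposited as 2 tables, each holding the siNC and siPC4 library of one number, and these are called pair 1 and pair 2. Each library's TPM values, which are scaled by gene length and library total, summed to between 996343 and 996814, so the sequencing depth is unknown. The first table listed 17598 genes and the second 17889, and the 16159 genes in both were compared. The labels do not say that the libraries of one group came from separate cultures. The p-values measure only how far the changes of these 2 pairs differ, which may be technical. They also draw on the spread of all genes through limma's prior, and do not measure the spread between libraries of one group. Changes are given as siPC4 against siNC on the log2(TPM + 1) scale, with the standard error (SE) of limma over the 2 pairs. This scale understates the change of genes with low values. Where a value under 1 is listed as 0 it can also overstate it, as for BIK in pair 2 (-2.77, against the authors' deposited -2.60).

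SUB1 was examined first, since it is the target of the knockdown. It lies on the plus strand of chromosome 5 from 32585605 to 32604185 (hg19). Its level was 91.1 TPM in siNC-1 and 5.10 TPM in siPC4-1, and 58.6 TPM in siNC-2 and 3.94 TPM in siPC4-2. The mean log2 change was -3.75 ± 0.17 (SE, n = 2 pairs; limma, adjusted p = 0.00622), in the direction given by the labels in both pairs. With no replicate block the adjusted p was 0.171.

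**Figure D1:**
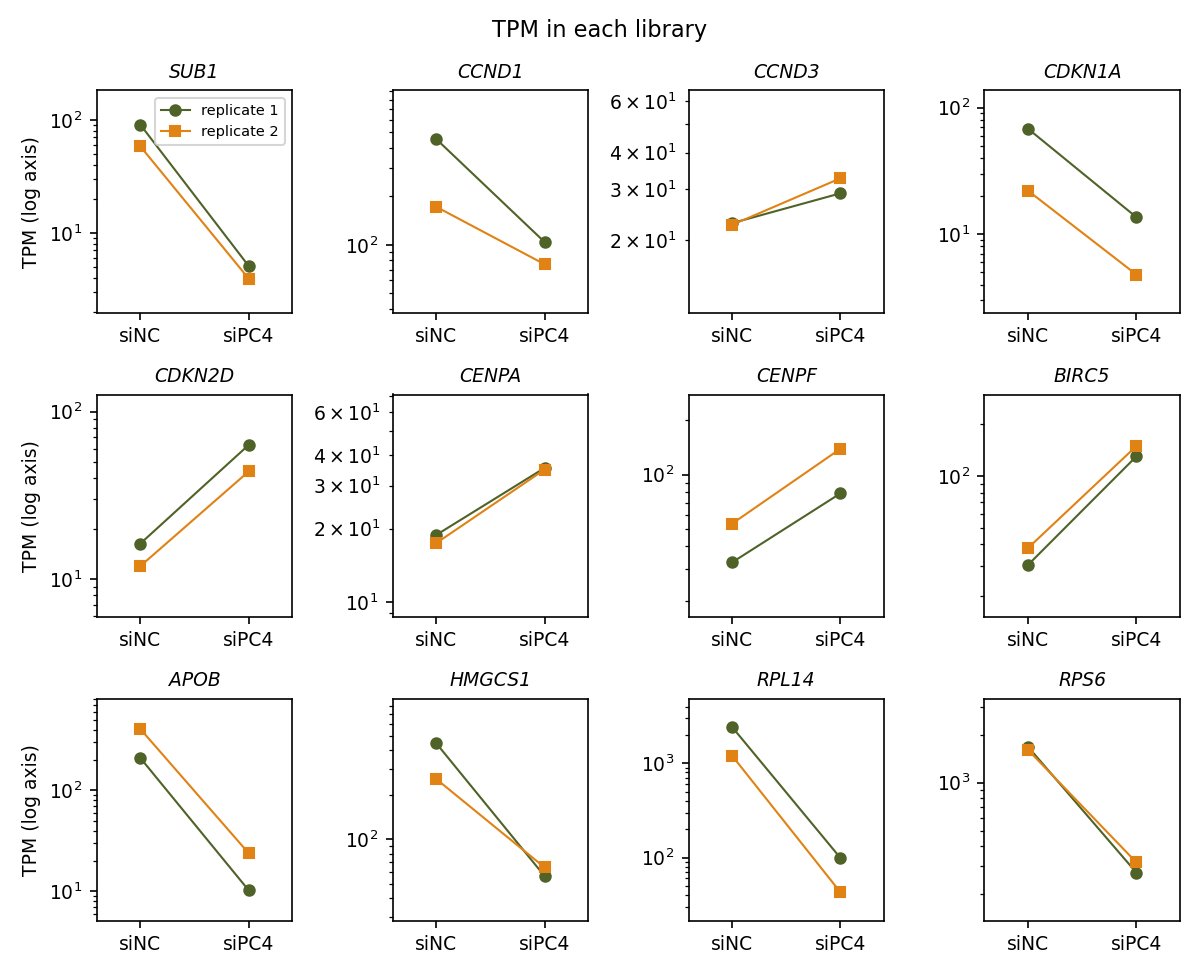
TPM of 12 genes in each of the 4 libraries, on a log axis that differs between panels. Points are single libraries, and a line joins the siNC and siPC4 library of one replicate number. SUB1 lay at 91.1 and 58.6 TPM in siNC and at 5.10 and 3.94 TPM in siPC4.

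The series title names D-type cyclins, the partners of CDK4 and CDK6 in early G1, so these genes and their partners and inhibitors were compared as a list fixed before the data were examined. CCND1 (chromosome 11, 69455873 to 69469242, hg19), which encodes cyclin D1, fell from 455 to 104 TPM in pair 1 and from 172 to 75.7 TPM in pair 2. Its mean log2 change was -1.65 ± 0.25 (SE, n = 2 pairs; limma, adjusted p = 0.0183). CCND3 did not pass the test, with 22.9 and 29 TPM in pair 1 and 22.6 and 32.6 TPM in pair 2 (limma, adjusted p = 0.0936). CCND2 was not among the genes listed in both tables and is not analysed here. Of the 14 measured members of the list, 4 rose, 4 fell and 6 did not pass, and the counts adjusted over the list alone were also 4 and 4. The members that rose were CDKN2D, an inhibitor of CDK4 and CDK6, by 1.85 ± 0.14, CDK6 by 1.43 ± 0.15, and the pocket proteins RBL2 by 1.1 ± 0.15 and RBL1 by 0.98 ± 0.16. Beside CCND1, the CDK inhibitors CDKN1A and CDKN1C had log2 changes of -2.12 ± 0.16 and -1.17 ± 0.18, and CDK4 one of -0.50 ± 0.13 (limma, adjusted p = 0.0481). The list as a whole was not called (camera, adjusted p = 0.68, and adjusted p = 0.843 with an estimated correlation).

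The title also names centromere proteins. Of 27 measured genes of this list, 7 rose, 0 fell and 20 did not pass, with 7 and 0 adjusted over the list alone. CENPF, a large kinetochore protein of late G2 and mitosis, rose by 1.31 ± 0.13 (limma, adjusted p = 0.0102), from 32.5 to 78.7 TPM in pair 1 and from 53.4 to 139 TPM in pair 2. CENPA, the histone H3 variant of centromeric chromatin, rose by 0.92 ± 0.15 (limma, adjusted p = 0.0196), from 18.8 to 35.4 TPM and from 17.4 to 34.9 TPM. The others were CENPBD1 (1.63 ± 0.16), INCENP, a subunit of the chromosomal passenger complex (0.88 ± 0.13), CENPT (0.82 ± 0.17), CENPL (0.71 ± 0.17) and CENPH (0.70 ± 0.17). The list was not called against other genes (camera, adjusted p = 0.222, and adjusted p = 0.843 with an estimated correlation), and CENPH and CENPL did not pass after median scaling.

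Across all genes, 4165 of 16159 passed the threshold, 2740 of which rose and 1425 fell. All of them moved the same way in both pairs. The blocked test cannot pass a gene with opposite signs, so this is no measure of how well the pairs repeat. Among them 1145 rose and 956 fell at least 2-fold. Among the largest falls with all 4 values above 0 were those of NPPB, the precursor of B-type natriuretic peptide (-5.31 ± 0.62), RPL14 (-4.70 ± 0.13), APOB, the main protein of low-density lipoprotein (-4.14 ± 0.14), and MATN3 (-4.11 ± 0.15). They were followed by CLU (-3.96 ± 0.17), the Wnt antagonist DKK1 (-3.88 ± 0.18), PAPSS2 (-3.85 ± 0.15) and C4orf48 (-3.81 ± 0.34). IHH, a hedgehog ligand, went from 59.4 TPM to a listed 0 in pair 1 and from 36.7 to 1.13 TPM in pair 2. The largest rises with all values above 0 were those of the histone genes HIST1H2BD (4.14 ± 0.33), HIST1H2BJ (3.32 ± 0.18) and HIST1H2BG (3.05 ± 0.19) and of the tRNA gene TRNAS12 (3.21 ± 0.53). SNORD49A, SPEF1 and LINC00324 were listed at 0 in both siNC libraries and at 10.4 and 11, 10.8 and 10.4, and 9.71 and 6.35 TPM in siPC4-1 and siPC4-2. TRNAG4, MIR5581 and HIST1H2AE were listed at 0 in siNC-1 alone and lay at 19.6, 8.17 and 14.2 TPM in siPC4-1. Values of tRNA, microRNA and small nucleolar RNA genes are uncertain, since such short genes can overlap longer ones and the library kit does not mark strand.

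The number of calls rested on the replicate block. With no replicate block limma called 0 genes (2776 at an unadjusted p under 0.05, against 7323 with the block). Fits with a single library left out, also those of the lists below, have no block. A call that ended in them cannot be laid to that library alone. With the block, 1657 genes were called with a pseudocount of 0.1 and 2120 without a mean-variance trend. The direction split rested on the scaling: the median log2 change of all genes was 0.251, and after median scaling, which lowered it to 0.105, 1651 genes rose and 1837 fell (47.3% higher, against 65.8%). All 1425 falls were called again as falls, and 1651 of the 2740 rises as rises. Median scaling lowers the mean log2 change of every gene by the same amount. Each fall thus became larger, and the return of all falls is no check on them.

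**Figure D2:**
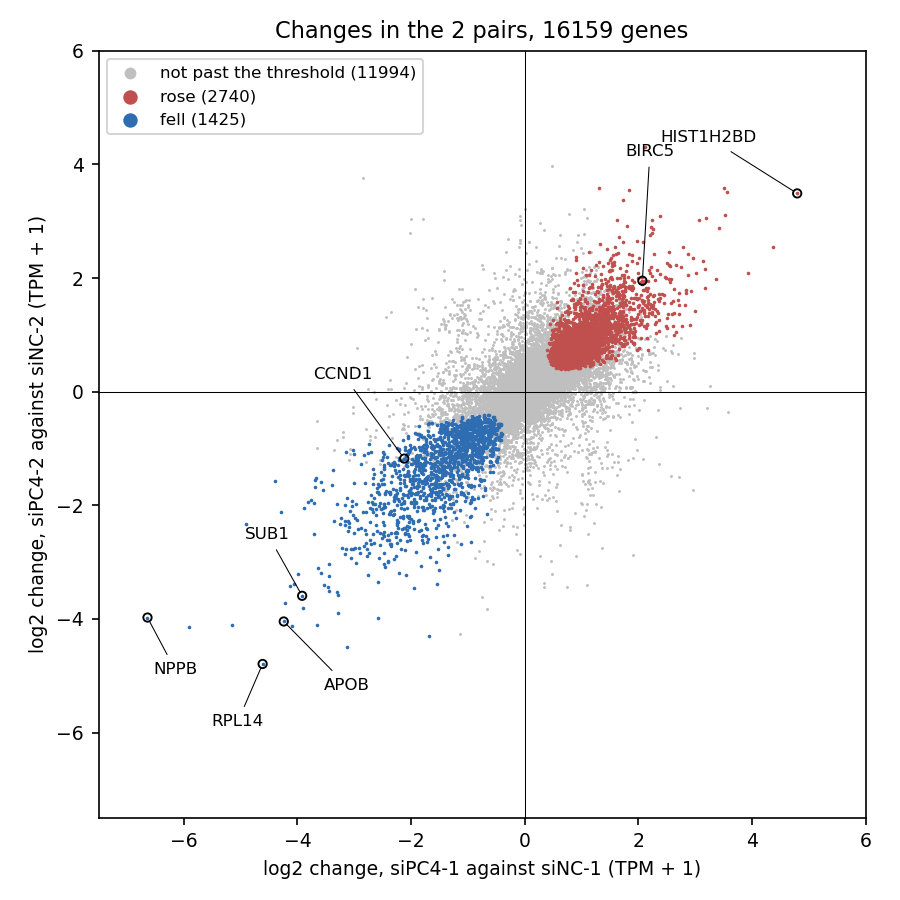
Log2 change of 16159 genes in pair 1 (x axis) against pair 2 (y axis), on the log2(TPM + 1) scale. Each point is a gene, red where it rose (2740) and blue where it fell (1425) in limma with the pair as a block, and grey where it did not pass. The genes named on the plot are ringed, and Pearson's r across genes was 0.703.

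Genes of the hepatocyte list, which holds secreted plasma proteins and liver transcription factors, fell in larger number than those of any other of the 26 lists. Of 31 measured members 27 fell, 0 rose and 4 did not pass, with 30 falls adjusted over the list alone, and the median log2 change was -1.92 in pair 1 and -1.1 in pair 2. After APOB, the examples are the fibrinogen chain FGA (-2.61 ± 0.20, from 924 to 118 TPM and from 627 to 130 TPM), the fatty acid binding protein FABP1 (-2.35 ± 0.18) and the vitamin D binding protein GC (-2.27 ± 0.17). The list lay below other genes (camera, adjusted p = 4.61e-20). Camera's preset correlation takes the genes of a list as nearly independent. Where they move together, here and in the lists below, its p-values are too small as a measure of the libraries. With an estimated correlation the adjusted p was 0.649, but that setting called 0 of the 26 lists and also missed a list lowered in simulation. Markers of other cells moved in the same libraries. Of 7 biliary and progenitor markers 6 fell and 0 rose, also 6 adjusted over the list alone (camera, adjusted p = 7.58e-06, and adjusted p = 0.649 with an estimated correlation), among them SOX9 (-2.23 ± 0.25), KRT19 (-2.18 ± 0.24), SPP1 (-1.69 ± 0.24) and PROM1 (-1.13 ± 0.16). All 3 measured blood and endothelial markers fell, also 3 adjusted over the list alone (camera, adjusted p = 0.00363, and adjusted p = 0.649 with an estimated correlation). These were LYZ (-1.35 ± 0.28), CD68 (-1.08 ± 0.18) and CD14, which was listed at 0 in siPC4-2. Without siNC replicate 2, siPC4 replicate 1 or siPC4 replicate 2 the blood list was not called, with camera adjusted p values of 0.121, 0.146 and 0.127.

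Cholesterol synthesis genes fell in 18 of 23 cases and rose in 0, with 21 falls adjusted over the list alone and all 23 lower in both pairs. They included the sterol monooxygenase MSMO1 (-2.62 ± 0.15), HMGCS1 (-2.47 ± 0.26, from 446 to 56.4 TPM and from 256 to 64.5 TPM) and SREBF2, which encodes the transcription factor of this pathway (-2.37 ± 0.19). The list was called by camera (adjusted p = 6.57e-16) and, alone among the 26, by fry (adjusted p = 0.0172), with an adjusted p = 0.649 for camera with an estimated correlation. Of 15 fatty acid synthesis genes 7 fell and 0 rose, also 7 adjusted over the list alone. They included the desaturases SCD (-2.25 ± 0.18) and FADS2 (-1.83 ± 0.21), ELOVL6 (-1.76 ± 0.21) and the synthase FASN (-1.65 ± 0.13), with a camera adjusted p = 2.74e-06 and an adjusted p = 0.649 with an estimated correlation.

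A further pair of lists lay lower. Of 24 genes of the unfolded protein and integrated stress response 10 fell and 0 rose, with 12 falls and 1 rise adjusted over the list alone. The chaperones PDIA4 and HSPA5 of the endoplasmic reticulum had log2 changes of -1.42 ± 0.14 and -1.28 ± 0.15, CHAC1 one of -1.39 ± 0.23 and the cystine transporter SLC7A11 one of -1.07 ± 0.25. Of 23 TGF-beta, matrix and EMT genes 12 fell and 0 rose, with 13 falls and 2 rises adjusted over the list alone. The examples are the epithelial adhesion protein CDH1 (-2.65 ± 0.16), THBS1 (-2.51 ± 0.14), the membrane protease MMP14 (-2.29 ± 0.18) and TGFBI (-1.61 ± 0.12). The camera adjusted p was 3.91e-07 for the first list and 3.33e-08 for the second, and each had an adjusted p = 0.649 with an estimated correlation.

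Replication-dependent histone genes rose in 15 of 20 cases and fell in 0, also 15 and 0 adjusted over the list alone, with medians of 2.65 and 1.67 in the 2 pairs. HIST1H2BD went from 4.49 to 152 TPM in pair 1 and from 17.6 to 208 TPM in pair 2, and HIST1H2AD from a listed 0 to 5.92 TPM and from 1.89 to 15.9 TPM. The 5 members that did not pass lay at 8.03 TPM or less in every library. The values do not show what part of the histone RNA the library kit captured, so the rises hold only for the captured part. Single histone genes are uncertain, since near-identical copies can share reads. The camera adjusted p was 7.8e-06, and the adjusted p = 0.773 with an estimated correlation.

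Genes of the kinetochore and spindle checkpoint rose in 11 of 30 cases and fell in 0, with 15 rises and 1 fall adjusted over the list alone. BIRC5, or survivin, rose by 2.01 ± 0.13, from 30.2 to 130 TPM and from 37.9 to 149 TPM, ZW10 by 1.65 ± 0.18, SKA2 by 1.59 ± 0.18 and NDC80 by 0.83 ± 0.13. Of 30 G2/M genes 9 rose and 0 fell, with 10 rises adjusted over the list alone, among them the kinesin KIF4A (1.4 ± 0.27), HMMR (1.2 ± 0.15) and the mitotic kinases PLK1 (0.86 ± 0.13) and AURKA (0.65 ± 0.12). The kinetochore list was called by camera (adjusted p = 0.0095), as was the G2/M list (adjusted p = 0.0145), and each had an adjusted p = 0.843 with an estimated correlation. After median scaling 7 kinetochore genes rose and 1 fell, and 4 G2/M genes rose and 0 fell, with AURKA not past the threshold (limma, adjusted p = 0.051). The kinetochore call ended without siNC replicate 2 (camera, adjusted p = 0.0875) and without siPC4 replicate 2 (0.135). The G2/M call ended with no replicate block (0.0796), without a mean-variance trend (0.0612), and without siNC replicate 2 (0.983), siPC4 replicate 1 (0.326) or siPC4 replicate 2 (0.0646).

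General transcription factor and Mediator genes rose in 12 of 32 cases and fell in 2, with 21 rises and 2 falls adjusted over the list alone. The TFIIH subunit GTF2H3 rose by 1.8 ± 0.17, TAF1, the largest subunit of TFIID, by 1.51 ± 0.22, the TFIIF subunit GTF2F2 by 1.33 ± 0.18 and the polymerase subunit POLR2D by 1.27 ± 0.16. The list was called by camera (adjusted p = 0.00374), with an adjusted p = 0.649 with an estimated correlation. The call ended without siNC replicate 2 (0.0544) and without siPC4 replicate 1 (0.127), and after median scaling 5 members rose and 2 fell.

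Of 47 cytosolic ribosomal protein genes 7 fell, 1 rose and 39 did not pass, with 3 falls and 0 rises adjusted over the list alone. After median scaling 13 fell and 0 rose. RPL14 went from 2440 to 98.8 TPM in pair 1 and from 1210 to 42.7 TPM in pair 2, and RPS6 from 1684 to 274 TPM and from 1609 to 317 TPM (-2.48 ± 0.14). RPL37 and RPL10A had log2 changes of -0.95 ± 0.13 and -0.58 ± 0.12, and the median of the list was -0.24 in pair 1 and -0.25 in pair 2. Processed pseudogenes can share reads with these genes, so their values are uncertain. The camera adjusted p was 7.21e-09, with an adjusted p = 0.649 with an estimated correlation. The call ended after quantile normalization (0.222), without siNC replicate 1 (0.661) and without siPC4 replicate 2 (0.754).

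The NF-kappaB and inflammatory list had medians of opposite sign, 0.55 in pair 1 and -1.15 in pair 2, a difference that was not tested. Of 17 members 1 fell, also 1 adjusted over the list alone, and 0 rose. This was the chemokine CCL20 (-2.03 ± 0.30), while CXCL5 had 132 and 82.9 TPM in pair 1 and 226 and 27.7 TPM in pair 2 and TNFAIP3 had 36.5 and 30.9 TPM and 31.7 and 12 TPM, neither past the threshold. The list was called by camera (adjusted p = 0.0171) with an adjusted p = 0.843 with an estimated correlation, and the call ended without siNC replicate 2 (0.349) and turned its direction without siPC4 replicate 2 (0.9).

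**Figure D3:**
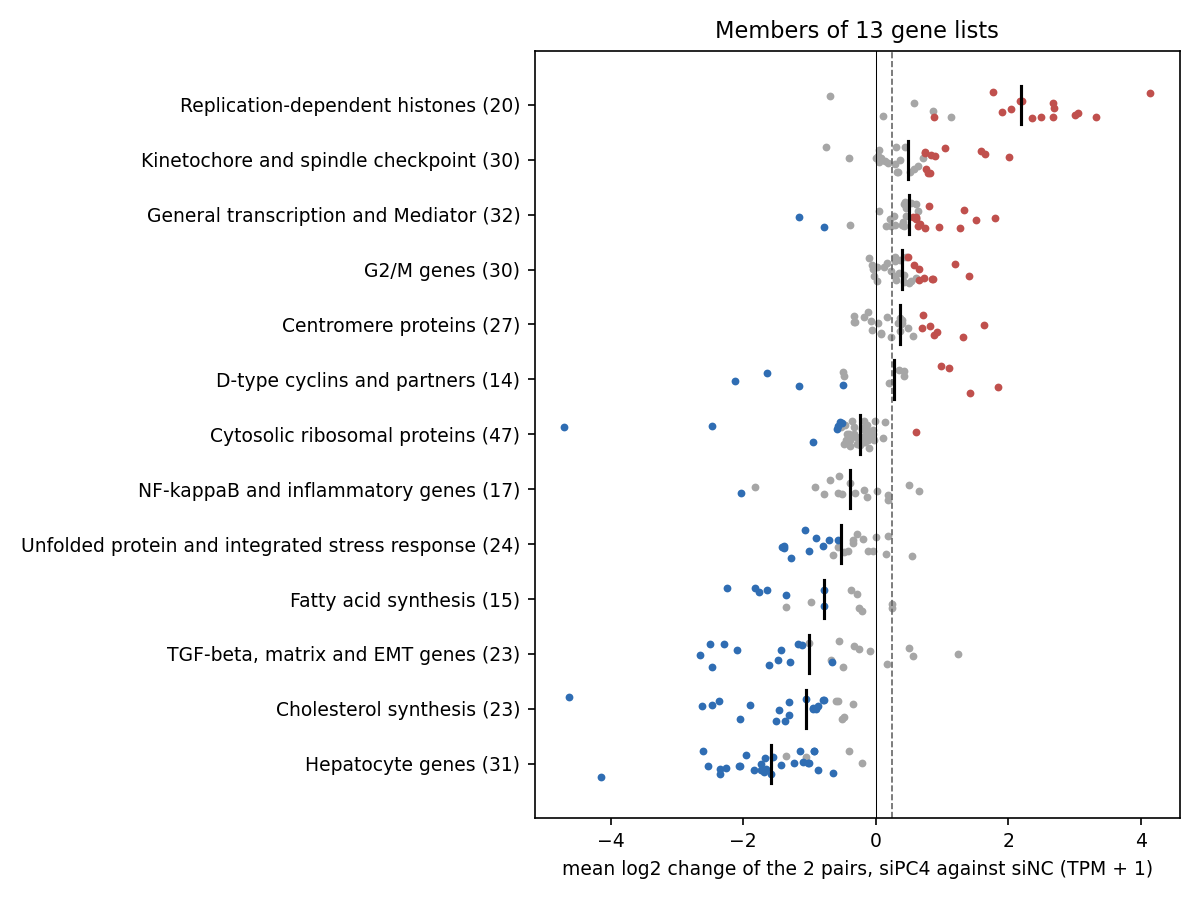
Mean log2 change over the 2 pairs of every measured member of 13 gene lists, with the number of members in parentheses. Points are genes, red where they rose, blue where they fell and grey where they did not pass, black bars are medians, and the dashed line is the median of all genes (0.251). Of 31 hepatocyte genes 27 fell, and of 20 histone genes 15 rose.

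The other lists were not called by camera. Of 36 DNA replication and G1/S genes 4 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.865). The rises were those of the GINS subunits GINS3 (1.36 ± 0.20) and GINS2 (0.72 ± 0.14) and of the transcription factors E2F1 (0.78 ± 0.14) and E2F8 (0.70 ± 0.16). After median scaling 3 rose and 3 fell, and E2F8 did not pass (limma, adjusted p = 0.0689). Of 26 homologous recombination and DNA damage genes 2 rose and 0 fell (0 adjusted over the list alone; adjusted p = 0.749), namely ATM (0.74 ± 0.17) and RAD51AP1 (0.65 ± 0.14), and neither passed after median scaling (limma, adjusted p = 0.0628 and 0.0589). Among 22 p53 target genes 1 rose and 2 fell (also 1 and 2 adjusted over the list alone; camera, adjusted p = 0.0579). The falls were those of GADD45A (-1.62 ± 0.21) and GADD45B (-1.47 ± 0.17). The p53 list leaves out CDKN1A and PMAIP1, p53 targets that fell and are counted in other lists. This list was called after median scaling (0.0454), after quantile normalization (0.0406) and without siPC4 replicate 1 (0.047). Of 22 glycolysis and hypoxia genes 3 rose and 4 fell (also 3 and 4 adjusted over the list alone; adjusted p = 0.0783), including falls of EGLN3 (-1.32 ± 0.31), NDRG1 (-1.06 ± 0.19), VEGFA (-1.04 ± 0.20) and LDHA (-0.59 ± 0.13). After median scaling 2 rose and 7 fell. With no block and 1 library left out, GADD45B turned its direction without siPC4 replicate 2 (0.068) and LDHA without siNC replicate 1 (0.066), in fits that take in the difference between the tables, while within the pairs they had log2 changes of -1.24 and -1.71, and of -0.66 and -0.52. Of 30 oxidative phosphorylation genes 5 rose and 0 fell (also 5 and 0 adjusted over the list alone; adjusted p = 0.0579), including SDHB (0.85 ± 0.15), CYCS (0.74 ± 0.15) and NDUFS3 (0.73 ± 0.14). This list was called after quantile normalization (0.00446), with no filter (0.0227), with a pseudocount of 0.1 (0.0452) and without mitochondrial and rRNA genes (0.0418).

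Of 33 mRNA stability and decay factors 7 rose and 4 fell (9 and 4 adjusted over the list alone; camera, adjusted p = 0.68), including the deadenylase subunits PAN2 (1.45 ± 0.16), PAN3 (0.74 ± 0.16) and CNOT7 (0.59 ± 0.13) and the exonuclease XRN1 (0.96 ± 0.23). After median scaling 1 rose and 4 fell, and PAN3, CNOT7 and XRN1 did not pass (limma, adjusted p = 0.0573, 0.0735 and 0.0598). Of 19 interferon response genes 3 rose and 2 fell (3 and 3 adjusted over the list alone; adjusted p = 0.141), the rises being those of MX2 (1.33 ± 0.23), HERC5 (0.81 ± 0.19) and STAT2 (0.58 ± 0.14). After median scaling 1 rose and 3 fell, and HERC5 and STAT2 did not pass (limma, adjusted p = 0.063 and 0.0904). Of 20 apoptosis regulators 2 rose and 3 fell (2 and 4 adjusted over the list alone; adjusted p = 0.433). The falls were those of the survival factor BCL2L1 (-1.59 ± 0.20), of PMAIP1 (-1.44 ± 0.23) and of BIK, which was listed at 0 in siPC4-2. After median scaling 1 rose and 4 fell. None of the 15 mitochondrially encoded RNAs passed (0 adjusted over the list alone; adjusted p = 0.68), and their share of all TPM was 8.34% in siNC-1, 9.24% in siPC4-1, 18.1% in siNC-2 and 19.1% in siPC4-2. Of 6 fibroblast markers 2 rose and 1 fell (also 2 and 1 adjusted over the list alone; adjusted p = 0.68). Their rises were those of COL6A1 (1.13 ± 0.16) and of COL3A1, which was listed at 0 in both siNC libraries and lay at 2.17 and 5.58 TPM in siPC4. None of the 3 measured markers of cervical and kidney lines passed (0 adjusted over the list alone; adjusted p = 0.325).

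Members that passed against the main direction of their list, or beyond the named examples, were picked out after their values were seen. TBP, the TATA-binding protein, and the Mediator subunit MED12 were the 2 falls among general transcription genes (-1.16 ± 0.16 and -0.79 ± 0.18). The 4 falls among mRNA decay factors were those of IGF2BP3 (-0.55 ± 0.13) and of the ZFP36 family, which binds AU-rich elements and promotes decay: ZFP36L2 (-1.43 ± 0.23), ZFP36 (-1.02 ± 0.18) and ZFP36L1 (-0.86 ± 0.18). E2F2 fell among replication genes (-1.42 ± 0.21) and PDGFRA among fibroblast markers (-0.97 ± 0.23). OAS1 (-1.49 ± 0.37) and ISG20, which was listed at 0 in siPC4-2, were the falls among interferon response genes. The repair factor XPC rose among p53 targets (1.51 ± 0.14), as did the caspase inhibitor XIAP (0.68 ± 0.15) among apoptosis regulators. PFKL (1.35 ± 0.14), ENO2 (1.24 ± 0.15) and KDM3A (0.64 ± 0.14) rose among glycolysis and hypoxia genes, NDUFB5 (0.78 ± 0.15) among oxidative phosphorylation genes and RPL11 (0.60 ± 0.15) among ribosomal protein genes. XIAP, KDM3A and RPL11 did not pass after median scaling (limma, adjusted p = 0.0683, 0.065 and 0.0969).

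The 2 pairs share no library, and their log2 changes were compared across the 16159 genes. Pearson's r was 0.703 (0.695 to 0.711) and Spearman's rho 0.697, across genes, which are not independent replicates, and 80.8% of genes had the same sign. At least 2-fold in both pairs, 1113 genes were higher and 916 lower, against 268.4 and 141.4 for independent lists, and 144 had opposite directions, against 389.9. For crossed pairs (siPC4-1 against siNC-2 and siPC4-2 against siNC-1) r was 0.055 and 1340 genes changed at least 2-fold in both, against 2029. Crossing puts the difference between the tables into the 2 changes with opposite signs. This lowers r by construction, so the crossed value is no measure of how well the pairs repeat. With at least 5 TPM the number of genes changed at least 2-fold in both pairs was 1258, and with a pseudocount of 5 it was 730.

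Each pair alone holds 1 library per arm and so has no replicate check. In pair 1, 2344 genes were at least 2-fold higher in siPC4-1 than in siNC-1 and 1638 at least 2-fold lower, and in pair 2 the numbers were 1850 and 1395. With a pseudocount of 5 the 2 directions together came to 1485 genes in pair 1 and 1140 in pair 2, against 3982 and 3245, and with at least 5 TPM to 2300 and 1800. Among genes called in the authors' deposited table of pair 1, HIST1H2BD had the largest change upward on the log2(TPM + 1) scale (4.80), followed by TRNAG4 and HIST1H2AE, and NPPB the largest downward (-6.64), followed by IHH. In pair 2, on the same scale, TRNAS12 (4.30) and the short genes MIR4786 and TRNAV11, both listed at 0 in siNC-2, lay highest, and RPL14 (-4.79), C4orf48 (-4.49) and HCAR3, listed at 0 in siPC4-2, lowest. The order rests on that scale: by the authors' deposited log2 changes TRNAG4 lay above HIST1H2BD (5.08) in pair 1, and IHH (-5.02) below RPL14 (-4.82) in pair 2. Set among 10000 random lists matched on mean expression, the hepatocyte median lay at percentile 0 and the histone median at percentile 100 in both pairs. The G2/M median lay at percentile 53.1 in pair 1 and 99.9 in pair 2, and that of D-type cyclins and partners at 24.5 and 95.6.

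The authors' deposited tables call 1441 genes in pair 1, 687 higher and 754 lower, and 991 in pair 2, 399 higher and 592 lower, each from 1 library against 1. Of these, 676 genes are called in both of the authors' deposited tables. There 281 are higher in both, against 16.5 for independent lists, 394 are lower in both, against 26.2, and 1 has opposite directions, against 42.2. At an authors' q under 0.001 the tables share 407 calls.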

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

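The items below are those whose change had opposite signs in the 2 pairs, each of 1 library per arm. The differences between the pairs were not tested, and no technical or biological explanation was tested for them. The median log2 change of the NF-kappaB and inflammatory list was 0.55 in pair 1 and -1.148 in pair 2, at percentiles 96 and 0 of random lists matched on mean expression. The p53 target genes had medians of 0.011 and -0.13, the mitochondrially encoded RNAs 0.301 and -0.016, and the fibroblast markers -0.156 and 0.287. The tRNA gene TRNAV11 had log2 changes of -2.841 and 3.756, from 6.17 TPM to a listed 0 in pair 1 and from a listed 0 to 12.5 TPM in pair 2.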

How the results depend on the processing

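The protein-coding, restored-value, all-library and mitochondrial alternatives were chosen after the data had been seen. The block decided the calls: with no replicate block limma called 0 genes (2776 at an unadjusted p under 0.05; smallest adjusted p 0.171), and SUB1 (-3.755) had an adjusted p of 0.171. In this balanced design the block cannot change a log2 change, so equal values in the 2 fits say nothing about stability. With 1 library left out, no block can be fitted with residual degrees of freedom, so these fits have no block and assume that the lone library varies like the other group. They called 0 genes each (1321 to 2182 unadjusted), 8 to 12 lists (8 without siNC replicate 2 and without siPC4 replicate 2, 13 with all 4 libraries), and put SUB1 at -4.069 to -3.441 (adjusted p 0.246 to 0.333). The calls were lost with fewer samples and the table difference left in the spread. In the pair left when replicate 1 or 2 was dropped, SUB1 changed by -3.592 or -3.917.

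Over the fits with 1 library left out, the direction of some named genes turned, with ranges of -3.017 to 0.068 (GADD45B), -1.54 to 0.908 (SFN), -1.24 to 0.066 (LDHA), -0.023 to 0.77 (ND6), -0.338 to 1.034 (ND2), -0.521 to 1.301 (CYTB), -0.121 to 0.734 (ND5) and -1.421 to 2.335 (TRNAV11). All of these but TRNAV11 had the same sign in both pairs. With no block, part of the difference between the 2 libraries of the full group enters the log2 change, as for GADD45B, at 339 TPM in siNC-1 and 54.3 TPM in siNC-2, with -1.24 and -1.71 within the pairs. The camera adjusted p of the NF-kappaB list ranged from 1e-06 to 0.9, and its direction turned without siPC4 replicate 2 (0.9).

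The number of genes called was 1657 with a pseudocount of 0.1 and 2120 without a trend, against 4165, and 3488 to 5018 in the other blocked settings. Of the 4165 calls, 1656 and 1704 were called again in those first 2 settings, 3076 after median scaling and 3564 after quantile normalization, which gave 2206 rises and 2108 falls. Pearson's r between the pairs was 0.586 with no filter, 0.802 with at least 5 TPM, 0.533 with a pseudocount of 0.1, 0.784 with a pseudocount of 5 and 0.055 for crossed pairs. Genes changed at least 2-fold in both pairs numbered 1258 with at least 5 TPM, 730 with a pseudocount of 5 and 1340 for crossed pairs, against 2029. In pair 1 there were 2300 and in pair 2 1800 with at least 5 TPM, and 1485 and 1140 with a pseudocount of 5. The stricter filter tests fewer genes and the larger pseudocount shrinks low genes by construction. Crossed pairs take in the difference between the tables with opposite signs, which lowers r by construction. For the other shifts the cause was not tested. At an authors' q under 0.001, 407 calls were shared, against 676. Depth is unknown, so no limit from it can be given, and genes under 1 TPM are listed as 0.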

Other observations

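The families, the split into protein classes, the strata of GC content and length, the word search on ranks, the test of ribosomal protein genes as a class and the tests of pseudogenes for each gene apart were chosen only after the result was seen. Genes were grouped by 16 phrases of the authors' description column, and the share called in each was compared with that of all other tested genes by Fisher's exact test, two-sided, adjusted over the 32 tests. Genes described as zinc finger proteins rose more often than others: 171 of 464 rose and 9 fell (36.9% against 16.4% of other genes, adjusted p = 4.98e-24), with median log2 changes of 0.77 in pair 1 and 0.63 in pair 2. After median scaling 116 rose (adjusted p = 6.71e-19). ZNF616 (2.72), ZNF429 (2.55) and ZNF678 (2.14) had the largest mean log2 changes, and many such genes are near copies that can share reads. Of 40 genes described as kinesins 16 rose (adjusted p = 0.00185), led by KLC2 (1.82), but 8 after median scaling (adjusted p = 0.174). Solute carriers, which move small molecules across membranes, fell in 48 of 233 cases and rose in 15 (20.6% against 8.65%, adjusted p = 2.36e-07), led by SLC51B (-3.44), SLC4A11 (-2.66) and SLC16A12 (-2.51).

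Of 16 genes described as serpins 10 fell and 0 rose (adjusted p = 8.61e-07), led by SERPINF2 (-2.83), SERPIND1 (-2.64) and SERPINA5 (-2.54), and of 17 described as apolipoproteins 8 fell and 0 rose (adjusted p = 0.000193), APOC3 (-2.35) and APOC1 (-1.87) after APOB. Of 84 mitochondrial ribosomal protein genes 19 rose and 0 fell, with fewer falls than other genes (0% against 8.86%, adjusted p = 0.00262), while the share of rises was 22.6% against 16.9% and did not pass (adjusted p = 0.316). Other families of membrane or matrix proteins did not pass for falls: genes described as transmembrane proteins (10.7% against 8.79%, adjusted p = 0.426), collagens (adjusted p = 0.416), G protein-coupled receptors (0.199), integrins (0.0871) and cadherins (1.0). By the reference proteins, of 1042 genes coding for a hydrophobic N-terminal segment only (an 11-residue window in the first 35 residues) 240 fell and 96 rose. Of 1505 coding for a membrane span only (a 19-residue window) 220 fell and 194 rose, of 928 coding for both 184 fell and 84 rose, and of 8643 coding for neither 631 fell and 1931 rose. The span-only genes had medians above 0 (0.083 in pair 1 and 0.101 in pair 2), below those of genes with neither (0.293 and 0.283). Genes are not independent, so the p-values above are too small as a measure of the libraries.

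The 3475 genes coding for such a segment, a span or both lay lower than the 8643 coding for neither by a median of -0.317 ± 0.024 in pair 1 and -0.28 ± 0.016 in pair 2 (bootstrap SE over genes), and 3 explanations were tested. The bound set beforehand for a class-wide shift was -0.3 in both pairs, so the smaller value leaves that hypothesis open. A bias by GC content or transcript length is argued against, since 97.1% and 97.3% of the difference was left after a smooth trend on both was removed, and 91.6% and 89.2% with strata in its place. Fewer Huh7 cells, or RNA of other cells mixed in, stays open: the SD of hepatocyte genes' changes was 1.18 times that of matched genes (0.773 against 0.656, with 95% of draws between 0.42 and 0.99), short of the bound set, although 0 of 4 lists of other cells' markers lay above all genes in both pairs.

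RPL14 and RPS6 fell, while the other 45 ribosomal protein genes of the list had medians of -0.214 in pair 1 and -0.246 in pair 2. Those medians argue against a fall of the whole class by the size seen in these 2 genes. The test of reads moving to pseudogenes was set beforehand for both genes together. The 1 pseudogene in both tables rose by 0.0908% at most of the TPM that the 2 genes lost. That pseudogene is one of RPS6, so the joint test could not show reads moving to copies of RPL14. Its rise was 0.173% at most of the loss of RPS6, which argues against reads of RPS6 moving to that copy. RPL14P1, the 1 RPL14 pseudogene listed, went from 4.61 TPM to a listed 0 in pair 1 and lay under 1 TPM in pair 2, so that it rose by 0.0857% at most of the TPM that RPL14 lost, while copies outside the authors' annotation were not searched. An effect of the knockdown on these 2 genes was not tested apart from these values.

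Falls shared by both siPC4 libraries may come in part from an siRNA that acts on other transcripts through its seed, if the 2 libraries received siRNAs with a seed in common, which is not settled here. Among 15642 words of 7 bases in the 3' UTRs of 11780 genes, the word that went most with falls in both pairs lowered its 693 genes by -0.148 and -0.142, between the bounds set beforehand (0.1 and 0.2). Its score was 1.12 times that of the next unrelated word, short of 1.5. On ranks another word came first, at -0.083 in both pairs. No single word stood apart, and the explanation is neither excluded nor borne out.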
